A study of Mus musculus with 8 samples.

How the data were processed

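Whole liver RNA of 4 WT and 4 Huwe1_LKO mice was isolated with a column kit, and libraries were built and sequenced by a commercial provider, per the labels' protocols. The labels give chow feeding at will and an age of 1 year, and name no sex, litter, harvest time or batch. Samples were grouped by the genotype in their titles. Where the labels number the livers, nothing says that equal numbers mark a shared litter or day.

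Reads were mapped to mm10 and compared with DESeq2, per the submitters' processing notes, which give no version, and the aligner, the counting step and any filter are not given in the sources used here. The authors deposited 1 table of the whole comparison. Its expression columns hold a depth-normalized signal, 1 value per gene and group, per the file headers and the values themselves. Its log2 column holds the log2 fold change of KO over WT, per the file headers, and equals the log2 ratio of the 2 expression columns in every gene to within 4.71e-08. Its p-value columns hold the authors' unadjusted and adjusted p, per the file headers, and the adjusted p-value matched a Benjamini-Hochberg adjustment over all 16640 genes to within 1.74e-06, so no low gene had been set aside. The table also pairs each gene with an Entrez ID, a length and annotation terms.

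The low values show how the deposited signal was built. Genes with a single read in all lie on 8 distinct values of 8 times the mean of both columns, 707 genes in all, which are the inverse of 8 library size factors between 0.957 and 1.05. Sums of 2 of these steps matched 100% of 391 genes in the range of 2 reads and sums of 3 steps 100% of 271 genes in the range of 3 reads, to within 0.000100, where 3.215% and 7.025% would match by chance. The size factors were thus close to 1, which does not by itself show equal depth, as they also depend on composition, and the group values, already divided by them, sum to 17347886 and 17533080 normalized reads. A gene with 1 read has a deposited log2 fold change of 0.11 to 0.12 in size and a value above 0 in both groups, the lowest being 0.115. By these values the deposited fold changes are shrunken toward 0, most where reads are few, and the 2 group values are the shared mean split by that shrunken ratio. No source used here states this, and it was seen directly only in genes with few reads. Folds of low genes are understated, and a group whose libraries hold no read is not listed at 0.

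The design fixed before the data were examined called for a count model on the reads of each liver, or limma on values per liver. With 1 value per gene and group neither could be fitted, so gene calls are the authors' own, at an adjusted p under 0.05. The standard error of each log2 fold change was computed as its size divided by the normal score of the two-sided unadjusted p. This assumes a Wald test, which the notes do not state, and since the fold changes are shrunken no gene exceeded 0.57, so the spread of the most variable genes is understated. Its median was 0.32 for 3516 genes with a mean value from 10 to 100, 0.15 for 6597 genes up to 1000 and 0.13 for 2196 genes above, and 8.33%, 12.8% and 21.5% of them were called. Nothing in the labels says how the livers were collected beyond genotype. The authors' p-values rest on the variation among these 8 livers. The list tests compare genes with other genes and use no values per liver.

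The 43 gene lists were fixed before the data were examined. Members were matched by symbol (825) or by a synonym (1) of the same Entrez ID in RefSeq (GRCm38), in which 16608 of 16640 IDs were found, and 16 had no match in the table. These counts of members include a list of fasting-raised genes added later, which shares members with the PPAR-alpha list and supports no statement here. A spreadsheet had turned 26 symbols into dates, and these were replaced by the RefSeq symbol of the ID. Coordinates are those of RefSeq for GRCm38, the assembly named mm10 by the authors, counted from 1. Each list with 3 or more members at a mean value of 10 or more (12309 genes) was compared with all other genes by cameraPR of limma 3.58.1 in R 4.3.3, on the signed normal score of the deposited p, with an inter-gene correlation preset to 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation and the fry test need values per liver and were not run, so the correlation was varied instead. Centring moves all fold changes alike, but moves the scores by amounts that depend on each gene's standard error. These tests were not repeated after centring. Annotation terms with 15 to 300 tested genes were compared in the same way within each ontology. Random lists of the same size (10000 per list) were drawn from 50 bins of mean value. The trend of fold change with gene length and level was removed by subtracting the median of genes in the same class of both, with 5 classes of length and 10 of mean value. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

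On simulated data with the real genes' implied standard errors, 200 of 16640 genes were changed for the comparison of Huwe1_LKO with WT. The adjustment recovered 82% of those changed by 1 on the log2 scale and 32% of those changed by 0.5, with 3.39% of calls on unchanged genes. In 100 simulated draws of the fixed lists, 89% of 5 lists moved by 1 SD of the score were called, and 0.5% of lists left alone. Both rates hold only for the simulated scores and the correlation between genes assumed in them. They do not give the share of false calls among the real lists. The calls of the real lists changed with the correlation assumed, as described below.

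Named genes follow a rule set before the data were examined. They are Huwe1, the 12 largest rises and falls among called genes with a value of 1 or more in the higher group, up to 4 members per list with the smallest p and any further called member, and markers used in a check. Genes without an informative symbol were passed over, and some genes that the rule picks are not reported here. The rule also asked for no overlap between the values of the groups, which could not be applied. C3 and Mt1, described under other observations, were picked outside the rule. Cpt1a, Cyp7a1, Angptl4, Acaa1a, the uncalled fatty acid synthesis genes, S100a8 and the transcription factors Srebf1 and Mlxipl are members of fixed lists; those not called, and the genes of annotation terms, were named after their values were seen. Principal components, tests that leave out 1 liver, other splits of the livers, a replicate block and exact permutation tests need values per liver and are not analysed here.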

Results

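Livers of 8 mice aged 1 year and fed a chow diet were compared by bulk RNA sequencing of whole tissue. The 4 WT livers carried intact Huwe1, and the 4 Huwe1_LKO livers came from mice in which the gene was deleted in the liver only. Huwe1 encodes a large HECT-type ubiquitin ligase that marks proteins for degradation. The question, from the title of the series, was how loss of Huwe1 in the liver alters lipid metabolism and fatty liver disease. The data are the authors' deposited table of 16640 genes, with 1 normalized expression value per gene and group, a log2 fold change of Huwe1_LKO over WT, and p-values. The deposited group values summed to 17347886 for WT and 17533080 for Huwe1_LKO. Values per liver were not analysed here, so every level below is the authors' group value, and its error is the standard error of the log2 fold change that the deposited p implies.

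Huwe1 itself (Entrez ID 59026; chromosome X, 151800785 to 151935417 in GRCm38) was lower in the Huwe1_LKO livers. Its value in the authors' deposited table was 2666 in WT and 1784 in Huwe1_LKO, which leaves 66.9% of the WT level. The log2 fold change was -0.58, with an implied standard error of 0.13 and an adjusted p of 0.000425. Reads from liver cells other than hepatocytes, and from exons outside the deleted part, also count toward this value, and which exons were deleted is not given in the sources used here. Of 13 listed genes whose proteins are known targets of HUWE1, only Mfn2, a mitochondrial fusion protein, changed in the authors' deposited table, with a log2 fold change of -0.45 (adjusted p = 0.0439). Adjusted over the list alone, 0 passed. Mcl1 had a log2 fold change of 0.27 and Myc of 0.84 in the same deposited table, with adjusted p of 0.162 and 0.406, and neither passed. These are RNA levels. Protein levels, on which the ligase acts, were not measured here, so the values do not show whether its targets changed.

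By the authors' deposited table, 734 genes were higher and 925 lower in Huwe1_LKO at an adjusted p under 0.05, 9.97% of those listed. Among the genes that changed by 2-fold or more, 251 were higher and 201 lower. Crybb3, a beta-crystallin known from the eye lens, had the largest rise of any named gene, from 10.9 to 512 in the authors' deposited table (log2 fold change 5.55, implied standard error 0.35, adjusted p = 3.51e-54). Cidea, a lipid droplet protein, had the largest fall, from 812 to 24.9 in that deposited table (log2 fold change -5.03, implied standard error 0.46, adjusted p = 2.55e-24).

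Several other genes among the 12 largest rises are best known from tissues other than liver. Per the authors' deposited table, Tmeff2 rose by a log2 fold change of 4.20, the neuronal transcription factor Bhlhe22 by 4.15, gliomedin (Gldn) by 3.97, villin (Vil1), an actin bundler of brush borders, by 3.75, and the trefoil factor Tff3 by 3.72. Slc30a3, a zinc transporter of synaptic vesicles, rose by 3.61 and Tmem229a by 3.90 in the deposited table. Their levels stayed low even in Huwe1_LKO, between 41.2 for Gldn and 239 for Tmeff2 in the authors' deposited table. Higher levels were reached in Huwe1_LKO by Gstp2 (glutathione transferase pi), which went from 103 to 1688, by Pcp4l1, from 90.4 to 1067, by the C-type lectin Cd209c, from 27.6 to 455, and by the citrate transporter Slc13a5, from 19.1 to 263, per the authors' deposited table. Gstp2 shares long stretches of sequence with Gstp1, so reads of the pair may have been split between them.

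The largest falls included several genes of lipid handling. After Cidea came A4gnt, a glycosyltransferase of gastric mucins, with a log2 fold change of -4.44, and the stearoyl-CoA desaturase Scd1 with -3.21 in the authors' deposited table. Cidec (-3.13), a second droplet protein of the Cide family, the orphan receptor Gprc5b (-3.08), the phospholipid transfer protein gene Pltp (-3.02) and the calsyntenin Clstn3 (-2.86) followed in the deposited log2 fold changes. Malic enzyme (Me1, -2.81), Cyp2c38 (-2.72), acetyl-CoA carboxylase 2 (Acacb, -2.71), the exonuclease gene Pnldc1 (-2.44) and the fatty acid elongase Elovl5 (-2.44) complete the 12 largest falls in the authors' deposited table. Cyp2c38 belongs to a gene cluster of near-identical members, and its value is uncertain for that reason. The split into 734 higher and 925 lower genes depends on where the fold changes are centred. With the median of the most abundant eighth of genes set to 0, 1173 were higher and 622 lower, which moves the higher share from 44.2% to 65.3%.

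Genes of fatty acid and triglyceride synthesis fell almost as a block. Of 24 listed genes, 21 fell and 0 rose in the authors' deposited table, with a median log2 fold change of -1.13. Adjusted over the list alone, 21 fell. Scd1 (chromosome 19, 44394450 to 44407709 in GRCm38), which makes monounsaturated fatty acids, dropped from 229174 to 24826 in the authors' deposited table, 9.23-fold lower (implied standard error 0.30 on the log2 scale, adjusted p = 6.47e-24). Elovl5 (chromosome 9, 77917365 to 77984519), which lengthens polyunsaturated fatty acids, had the smallest p of the whole deposited table, with 13919 in WT, 2573 in Huwe1_LKO and an adjusted p of 8.42e-85. Me1, which supplies NADPH, was 7.01-fold lower, and Acacb, whose product malonyl-CoA restrains fatty acid entry into mitochondria, was 6.56-fold lower in the authors' deposited table. Fatty acid synthase (Fasn) went from 33089 to 7292 and the elongase Elovl6 from 3314 to 865 in the same deposited table. The transcription factors that drive the pathway moved less, with deposited log2 fold changes of -0.88 for Srebf1 (adjusted p = 0.00237) and -0.41 for Mlxipl, the gene of ChREBP (adjusted p = 0.015). The members that did not pass were Dgat2 (-0.29), Lpin2 (-0.36) and Lpin1 (-0.03), as log2 fold changes in the authors' deposited table. Against all other genes the list was lower by limma's camera test (adjusted p = 2.17e-39), and the call held at every preset correlation up to 0.5.

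Genes of lipid uptake and lipid droplets moved the same way, with 11 lower, 1 higher and 11 not passing among 23 listed in the authors' deposited table. The median log2 fold change was -0.39, camera gave an adjusted p of 5.95e-11, and adjusted over the list alone 11 fell. Pparg, the nuclear receptor that drives fat storage, fell from 515 to 121 (adjusted p = 1.82e-20) and Cidec, which enlarges droplets, from 534 to 61 (adjusted p = 5.16e-16) in the authors' deposited table. Fabp2, a fatty acid binding protein, was 2.95-fold lower, the fatty acid translocase Cd36 4.73-fold, the droplet budding protein Fitm1 5.00-fold and the droplet coat protein Plin4 4.83-fold, per the authors' deposited table. The 1 gene that rose was the fatty acid transporter Slc27a1, from 145 to 243 in the deposited table (adjusted p = 0.0012). Mogat1, a monoacylglycerol acyltransferase in both this list and the synthesis list, had a deposited log2 fold change of -1.86 (adjusted p = 0.0121).

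**Figure D1:**
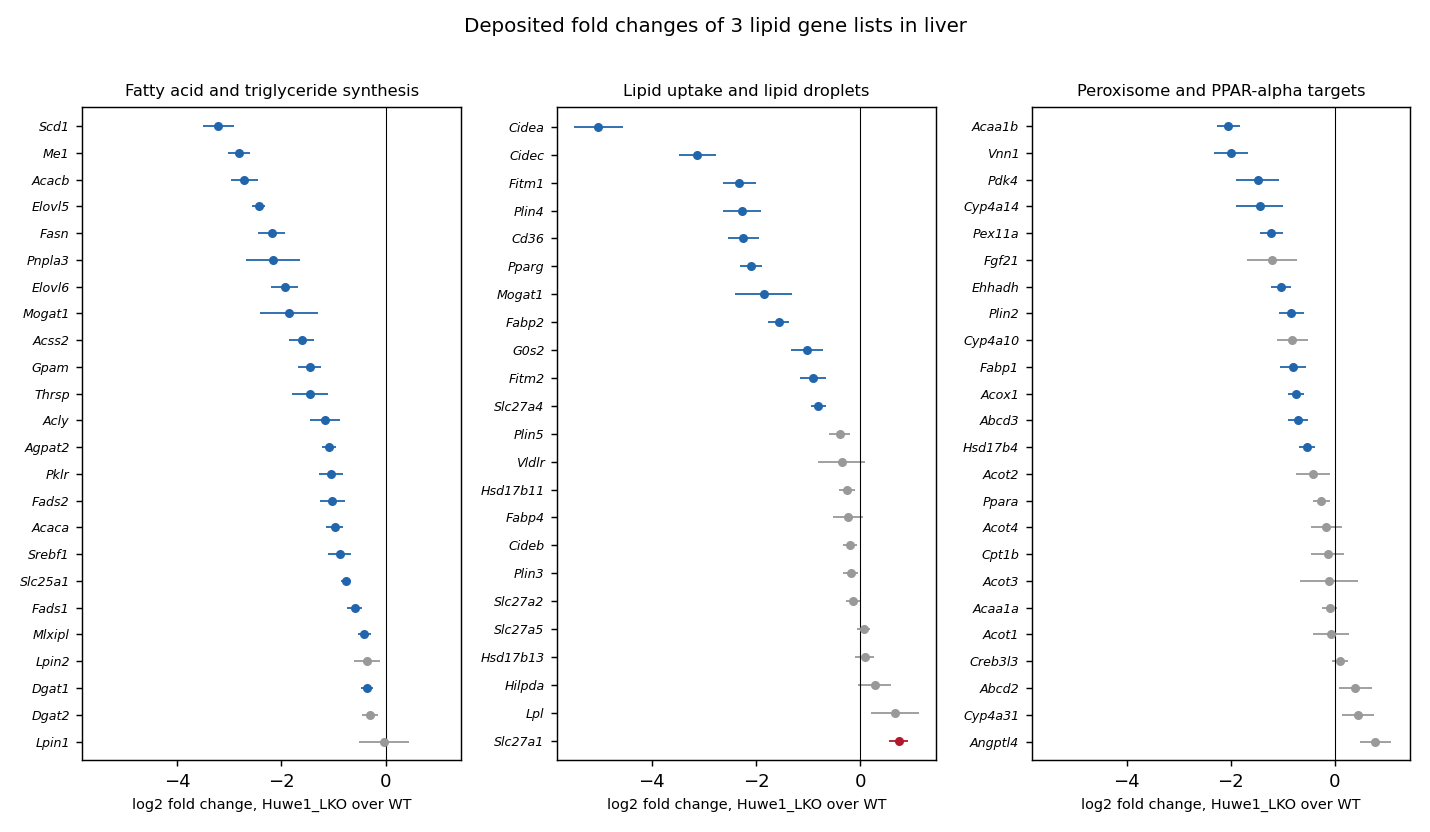
Log2 fold change of Huwe1_LKO over WT from the authors' deposited table for each listed gene of 3 fixed lists, with bars for the standard error that the deposited p implies. Blue points passed an adjusted p of 0.05 as lower, red as higher, and grey did not pass. All 24 synthesis genes lie left of 0, and 21 of them passed.

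Genes of fatty acid breakdown were lower as well. Among PPAR-alpha targets and peroxisomal genes, 11 of 24 fell and 0 rose in the authors' deposited table, with a median log2 fold change of -0.62 and a camera adjusted p of 6.23e-06. Adjusted over the list alone, 13 fell and 1 rose, the last being Angptl4, an inhibitor of lipoprotein lipase, with a log2 fold change of 0.78 and an adjusted p of 0.0842 over all genes. The peroxisomal thiolase Acaa1b fell from 35006 to 8485, the pantetheinase Vnn1 from 1536 to 386 and the bifunctional enzyme Ehhadh from 7043 to 3446 in the authors' deposited table. Pex11a, which divides peroxisomes, had a deposited log2 fold change of -1.22 (adjusted p = 4.44e-06). Acaa1b has a close copy in Acaa1a, whose deposited log2 fold change was -0.10, so the share of reads given to each is uncertain. For mitochondrial fatty acid oxidation, 5 of 20 genes fell and 0 rose (adjusted over the list alone, 6 fell), with a median log2 fold change of -0.22. Among them were Eci1 (-0.63), Hadh (-0.62), Acads (-0.49) and the carnitine carrier Slc25a20 (-0.38), as log2 fold changes in the authors' deposited table. Cpt1a, the gate of fatty acid entry into mitochondria, stood at 6287 in WT and 6323 in Huwe1_LKO in the authors' deposited table and did not pass. Camera called the oxidation list lower (adjusted p = 0.00403), a call lost once the dependence of fold change on gene length and level was removed (adjusted p = 0.138).

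Some cholesterol genes fell too. Of 25 genes of cholesterol synthesis and uptake, 9 fell and 0 rose in the authors' deposited table (adjusted over the list alone, 10 fell), with a median log2 fold change of -0.45 and a camera adjusted p of 0.00022, and 0.0915 at a preset correlation of 0.1. The cytosolic thiolase Acat2 fell from 2214 to 954 in the authors' deposited table. Dhcr7 had a deposited log2 fold change of -0.71 (adjusted p = 0.0149). In bile acid synthesis and transport, 7 of 21 genes fell and 0 rose (adjusted over the list alone, 10 and 3), with a camera adjusted p of 0.00475. Cyp8b1, which sets the share of cholic acid, fell from 9256 to 3206 and Cyp27a1 from 8076 to 4252 in the authors' deposited table, the export pump Abcb11 had a log2 fold change of -0.85, and the reductase Akr1d1 one of -0.73. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a deposited log2 fold change of 0.22 and did not pass (adjusted p = 0.79). Genes of lipolysis and lipoprotein export went both ways in the authors' deposited table, with 6 lower and 1 higher of 24 (adjusted over the list alone, 7 and 2). The lysosomal lipase Lipa (-0.93), Mgll (-1.03) and Apoa4 (-1.64) fell and Apoa1 rose (0.52), as log2 fold changes in the deposited table. The camera call of the lipolysis list as lower (adjusted p = 0.0347) was lost at a preset correlation of 0.05 (adjusted p = 0.154), and that of the bile acid list when the length and level trend was removed (adjusted p = 0.0831).

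Sugar and amino acid metabolism changed in part. Of 22 genes of glycolysis and gluconeogenesis, 7 fell and 2 rose in the authors' deposited table (adjusted over the list alone, 9 and 3). Ketohexokinase (Khk), the entry enzyme of fructose, fell from 7678 to 4597 and glycogen phosphorylase (Pygl) from 7201 to 4247 in that deposited table. Pfkfb3, an activator of glycolysis, rose from 302 to 1018 (adjusted p = 3.93e-06) and the glycogen synthase Gys2 from 3291 to 5665 (adjusted p = 0.000166) in the authors' deposited table. Of 25 amino acid and urea genes 5 fell and 1 rose in the deposited table (adjusted over the list alone, 6 and 1), among them Shmt1 (-0.82), Bhmt of the methionine cycle (-1.04) and the urea cycle gene Otc (-0.31) as log2 fold changes. Camera called both lists lower (adjusted p = 0.00981 for sugar and 0.0297 for amino acid genes), and neither at a preset correlation of 0.05 (adjusted p = 0.075 and 0.144) or with the length and level trend removed (adjusted p = 0.153 and 0.392).

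Detoxification genes split by member. Cytochrome P450 genes counted 4 higher and 4 lower of 20 in the authors' deposited table (adjusted over the list alone, 5 and 6). Cyp2c38 and Cyp2c29 (-1.12) fell, as did Cyp2c39, from 60.1 to 15.1, while Cyp2c70, which makes the muricholic acids of mice, rose (0.82), with log2 fold changes and levels from the authors' deposited table that shared reads within this family make uncertain. Of 23 glutathione and NRF2 target genes, 3 rose and 4 fell in the authors' deposited table (adjusted over the list alone, 3 and 6). Gstp1 rose from 19056 to 50685 and Gclm, which supports glutathione synthesis, from 2168 to 2988, while Gstm4 fell from 1541 to 779.9 and Ugdh from 4088 to 2589.9, per the authors' deposited table. Neither list was called by camera (adjusted p = 0.352 and 0.217), but with log2 fold change as the statistic the P450 list was called lower (adjusted p = 0.0211).

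Plasma proteins of the acute phase rose. All 21 listed genes had a log2 fold change above 0 in the authors' deposited table, the median was 0.83, and 6 passed over all genes against 11 adjusted over the list alone. Haemopexin (Hpx), the haem carrier of plasma, rose from 54703 to 129043 (adjusted p = 0.00102), orosomucoid 2 (Orm2) from 3338 to 13618 (adjusted p = 0.00637) and serum amyloid A3 (Saa3) from 94.3 to 296 (adjusted p = 0.00098) in the authors' deposited table. Socs3, a target of interleukin-6 signalling, had a deposited log2 fold change of 1.02, Itih4 of 0.86 and lipocalin 2 (Lcn2) of 1.60. Camera called the list higher (adjusted p = 5.57e-06). The implied standard errors of these genes had a median of 0.32 against 0.15 for lists of the same size matched on level. Neutrophil markers lay higher beside them, with 2 of 13 called in the authors' deposited table (adjusted over the list alone, 3). These were S100a9, from 25.6 to 79.1, and Retnlg, from 3.78 to 11.3, with S100a8 at a deposited adjusted p of 0.0504. Of 24 cytokines and chemokines, Cxcl14 alone rose, from 90.1 to 643 in the authors' deposited table (adjusted p = 1.42e-06; adjusted over the list alone, 1), while Nfkbia (0.44) and Il1b (0.94) did not pass. The camera calls of neutrophil markers (adjusted p = 0.0232) and of cytokines (adjusted p = 0.0232) as higher were both lost at a preset correlation of 0.05 (adjusted p = 0.0652 and 0.0983). None of 26 interferon-stimulated genes passed in DESeq2's deposited result, adjusted over all genes or over the list alone, and 0 had an unadjusted p under 0.05.

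Some growth, stress and clock genes changed. Cyclin D1 (Ccnd1) rose from 339 to 1032, the death receptor Eda2r from 13.4 to 33.7 and Plk2 from 113 to 172, while Bbc3, the gene of the killer protein PUMA, fell from 212 to 73.9 in the authors' deposited table. With Perp (-0.39) these make 3 higher and 2 lower of 21 genes listed as p53 targets in the deposited table (adjusted over the list alone, 3 and 2, with a camera adjusted p of 0.147). Ccnd1 is a cyclin that the fixed lists count there and not among the cell cycle genes. Of 25 cell cycle genes, cyclin E1 (Ccne1) alone rose, from 17.8 to 56.4 (adjusted p = 9.81e-06; adjusted over the list alone, 1), and Mki67, a marker of dividing cells, had a log2 fold change of 0.96 and did not pass in the authors' deposited table (adjusted p = 0.183; camera adjusted p for the list = 0.147, and 0.0032 with log2 fold change as the statistic). Ddit3 rose (0.76) and Atf5 fell (-0.77) among 20 genes of the integrated stress response (adjusted over the list alone, 1 and 1), and none of 21 genes of the unfolded protein response passed in DESeq2's deposited result, with 3 at an unadjusted p under 0.05. Of 19 clock genes, Dbp (0.59), Usp2 (1.18), Bhlhe41 (1.04) and Per3 (0.62) rose and Nfil3 (-0.81) and Arntl (-1.18) fell, as log2 fold changes in the authors' deposited table (adjusted over the list alone, 7 and 2). Markers of fetal liver and liver tumours included Tff3, alpha-fetoprotein (Afp), from 9.36 to 34.3, and Golm1, from 30.4 to 82 in the authors' deposited table, 3 higher and 0 lower of 14 (adjusted over the list alone, 4 and 1). Camera called the clock list (adjusted p = 0.0232) and the fetal list (adjusted p = 0.00621) higher, and the clock call was lost at a preset correlation of 0.05 (adjusted p = 0.0983), the fetal call with ranks in place of the signed scores (adjusted p = 0.0819).

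Few nuclear genes of oxidative phosphorylation passed the test. For oxidative phosphorylation, 29 of 30 genes had a negative log2 fold change in the authors' deposited table, with a median of -0.18, though only Ndufa10 of complex I (-0.42, adjusted p = 0.00501) and Sdha of complex II (-0.55, adjusted p = 0.0127) fell by the test, as they did adjusted over the list alone. Proteasome subunits had a median of -0.16, and 5 of 26 fell in the authors' deposited table (adjusted over the list alone, 6), Psmd11 (-0.42) and Psma1 (-0.29) with the smallest p. None of 30 cytosolic ribosomal protein genes passed in DESeq2's deposited result, while 2 had an unadjusted p under 0.05, and the median log2 fold change was -0.09. Camera called oxidative phosphorylation (adjusted p = 0.00774) and the proteasome (adjusted p = 0.00319) lower but not with the length and level trend removed (adjusted p = 0.291 and 0.323). Across the annotation terms of the deposited table, camera called 30 of 947 biological process, 20 of 254 cellular component and 22 of 329 molecular function terms. Fatty acid biosynthesis had the smallest p of the process terms (adjusted p = 7.2e-06, lower) and the mitochondrial inner membrane that of the component terms (adjusted p = 3.67e-07, lower), with 58 members lower and 3 higher of 288 tested. At a preset correlation of 0.05 fatty acid biosynthesis was the 1 term left (adjusted p = 0.0323).

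Genes that differ between the sexes changed in both directions. Of 15 female-biased liver genes, Cyp2c69 rose from 20.09 to 131, the transcription factor Cux2 from 7.97 to 27.7, Cyp3a44 from 4.96 to 15.6 and the prolactin receptor Prlr from 1664 to 2317, while Hao2 fell from 22.8 to 5.44 in the authors' deposited table (adjusted over the list alone, 5 rose and 1 fell). Of 16 male-biased genes, Elovl3 (-1.72), Ces2e (-0.92) and Mup7 (-1.17) fell and Susd4 rose (0.73), as log2 fold changes in the authors' deposited table (adjusted over the list alone, 4 and 3). Cyp2c69, Cyp3a44 and Mup7 have near-identical neighbours and are uncertain. Camera called neither list (adjusted p = 0.094 and 0.506), though it called the female-biased list higher with log2 fold change as the statistic (adjusted p = 0.00443). That call rests on the 11 female-biased genes past the filter on level. Their median log2 fold change was 0.44, against 0.07 for all 15. Y-linked genes were listed in both groups at like levels, with 731 in WT and 686 in Huwe1_LKO for Eif2s3y, 177 and 192 for Uty and 229 and 244 for Kdm5d in the authors' deposited table, and Ddx3y alone passed (0.46, adjusted p = 0.0466). Zonation genes went both ways, with 2 higher and 4 lower of 20 pericentral genes, such as Cyp27a1, Rgn (-0.41) and Cyp2a5 (0.89), and 2 and 1 of 19 periportal genes, such as Apoa4 and Igf1 (0.39), in the authors' deposited table. Adjusted over the list alone the numbers were 4 and 6 for pericentral and 3 and 2 for periportal genes, and camera called neither (adjusted p = 0.597 and 0.597).

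Few markers of other cell types passed the test. Hepatocyte markers were higher as a list (median log2 fold change 0.18, camera adjusted p = 0.00477, and 0.14 with log2 fold change as the statistic), with 4 of 14 called in the authors' deposited table (adjusted over the list alone, 5). Fetuin A (Ahsg) rose from 108033 to 194140 (adjusted p = 6.49e-17), Serpina1a, one of several near-identical copies, by a log2 fold change of 0.49 and the transcription factor Hnf4a by 0.37 in the authors' deposited table. In DESeq2's deposited result none of 18 macrophage, 14 endothelial, 15 stellate and fibroblast, 15 T and NK cell, 10 erythroid and 8 muscle markers passed, and 0, 1, 0, 0, 1 and 0 of them had an unadjusted p under 0.05. In the same order, 15, 9, 10, 13, 7 and 5 of them had a log2 fold change above 0. Their median implied standard errors ran from 0.20 for endothelial to 0.54 for T and NK cell markers. The lack of calls therefore does not show that cell makeup was unchanged. Camera called the T and NK cell list higher with log2 fold change as the statistic (adjusted p = 0.0166) but not in the main test (adjusted p = 0.237). Cholangiocyte markers had a median log2 fold change of 0.36 in the authors' deposited table and were not called as a list (camera adjusted p = 0.248). Single rises were seen in Jchain of plasma cells, from 69.7 to 208, and the collagen-binding Lum of the fibrosis list, from 113 to 188, in the authors' deposited table. Adrb3, listed as an adipocyte marker, rose from 148 to 643 (adjusted p = 1.79e-12), whereas the adipocyte genes Retn (-1.42) and Cfd (-1.23) did not pass in the authors' deposited table. Of the pancreatic enzymes Cela2a rose from 4.17 to 20.5 and Cela1 from 216 to 405, with the lipase Pnlip at 0.55 and 0.693 in the authors' deposited table. Among immediate early genes, which respond within minutes to handling of tissue, Ier3 alone rose (1.56) and Fos had a log2 fold change of 0.97 that did not pass in the authors' deposited table (camera adjusted p for the list = 0.147, and 0.0207 with log2 fold change as the statistic).

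**Figure D2:**
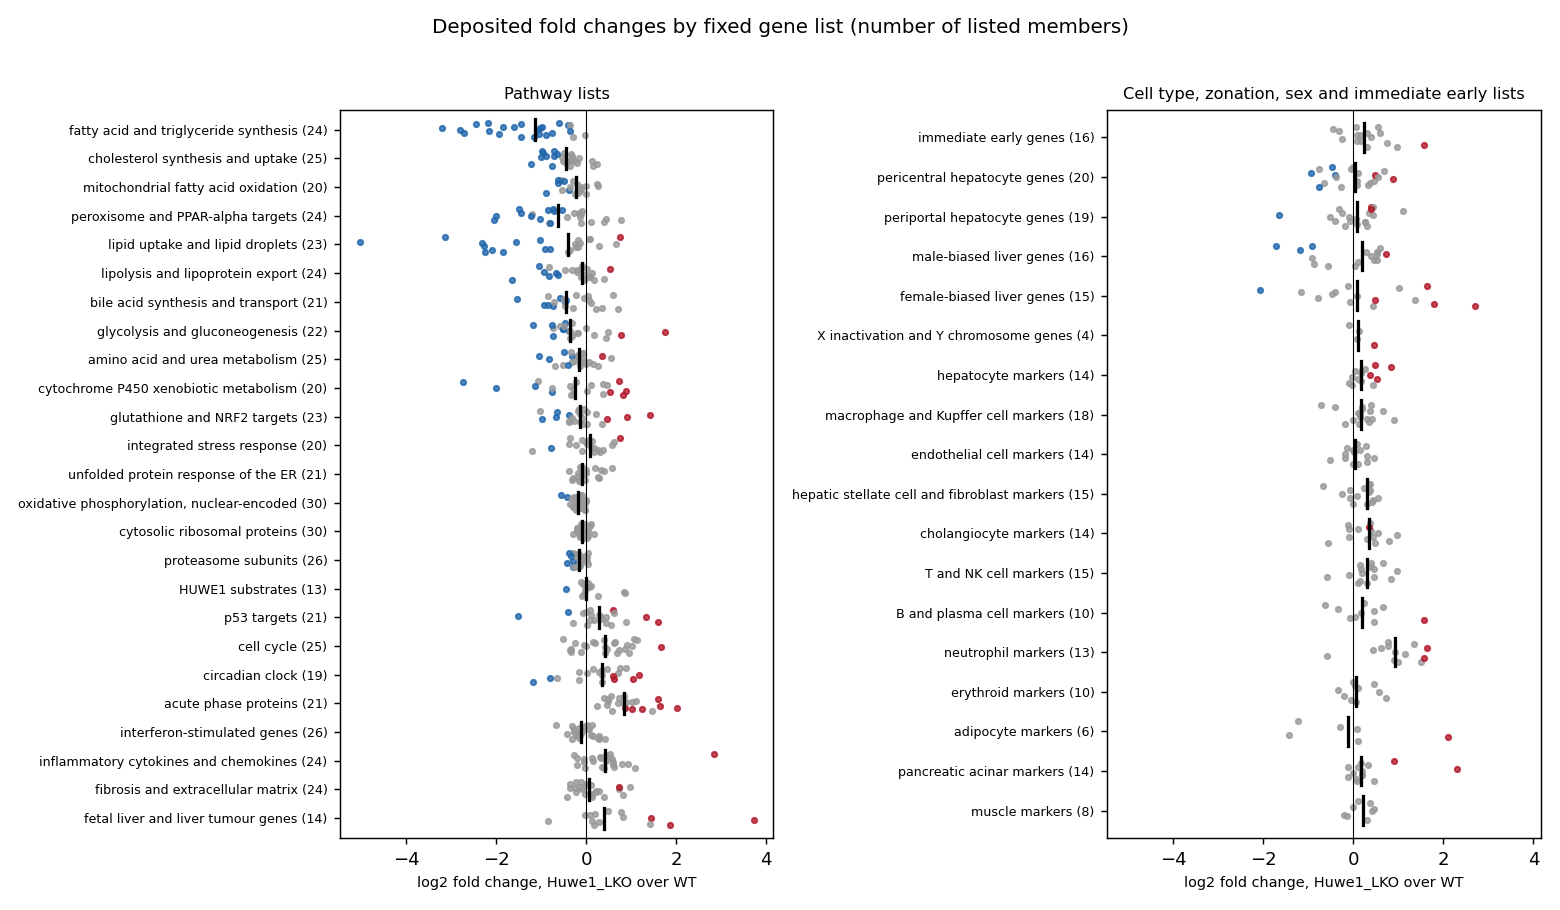
Log2 fold change of Huwe1_LKO over WT from the authors' deposited table for every listed member of the 43 fixed gene lists, 1 point per gene, with a black bar at each list's median. Blue points passed as lower, red as higher and grey did not pass. The median of fatty acid and triglyceride synthesis lies farthest left at -1.13, and those of acute phase proteins at 0.83 and neutrophil markers at 0.93 farthest right.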

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

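Except for the looser threshold and the list test without a filter, the alternatives below were chosen after the data were seen. With an adjusted p under 0.1 the deposited table gave 1010 genes higher and 1215 lower. Adjusting only genes with a mean of 10 or more, only genes with a higher group value of 17.4 or more, centring on the median of the genes with a mean of 10 or more, or removing the length and level trend each kept both counts within 1.5 times. Like counts do not mean the same genes. With the trend removed, 788 were higher and 896 lower, and these held 597 of the 734 higher and 734 of the 925 lower genes of the main result. Centring on the most abundant eighth raised the genes higher to 1173, since it adds the same amount to every fold change, and asking for a 2-fold change as well left 251 higher and 201 lower. Huwe1 had log2 fold changes from -0.59 to -0.50 over 8 alternatives. These settings move a fold change too little to turn the 24 genes with the largest changes, so their direction was not tested by them. The list calls depended on the correlation assumed between genes and on the statistic. From 6 lists higher and 11 lower, a preset correlation of 0.05 left 3 higher and 7 lower, and 0.1 left 1 higher and 3 lower, the acute phase list and the lists of fatty acid synthesis, PPAR-alpha targets and lipid droplets. Removing the length and level trend left 4 of the lists lower, these 3 and cholesterol synthesis, and the cause was not tested further. With log2 fold change as the statistic, camera also called the lists of T and NK cells (adjusted p = 0.0166), cell cycle (0.0032), female-biased (0.00443) and immediate early genes (0.0207) higher and cytochrome P450 genes lower (0.0211), and no longer called hepatocyte markers, glycolysis, oxidative phosphorylation and the proteasome. Ranks added the ribosomal proteins as lower and lost the fetal list. Of 72 annotation terms called, 1 was left at a correlation of 0.05. With the trend removed 36 terms were called, not all of them among the 72. No list called in the main test turned its direction. No paired analysis was possible because the deposited columns hold 1 value per group. DESeq2, RLE, upper-quartile, voom, strict count filters, quantile normalization, leaving out single livers, limma on values per liver, an estimated correlation and fry were planned and not run for the same reason. Depth limits what the table can show for low genes, whose fold changes are shrunken.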

Other observations

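The tests of annotation terms were planned, the genes named from them and the tests of fasting, clock genes, neutrophils and hepatocyte share, with their bounds, were chosen after the values were seen, and the tests of spread and of the length and level trend were set before theirs. Complement genes rose in Huwe1_LKO. Of 20 genes annotated to classical complement activation, 9 rose and 1 fell in the authors' deposited table (camera adjusted p = 0.00447, and 0.152 at a preset correlation of 0.05). The inhibitor Cfi rose from 8995 to 17267 (adjusted p = 3.09e-08), C8a from 7243 to 14406 (adjusted p = 4.17e-06) and C4a, a close copy of C4b, from 2180.5 to 5936 in the authors' deposited table. The central component C3, which is not among the genes of that term, went from 91989 to 222867 in the same deposited table (adjusted p = 8.37e-10). C3 and Mt1 were picked outside the rule for named genes. The metal-binding Mt1 rose from 893 to 4107 in the authors' deposited table, with an implied standard error of 0.56 on the log2 scale, next to the highest value that any gene reached (0.57), where the measure understates the spread.

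Genes of the tricarboxylic acid cycle fell, 8 of 23 annotated genes, with 0 higher in the authors' deposited table (camera adjusted p = 0.000472, and 0.0579 at a preset correlation of 0.05). Citrate synthase (Cs) fell from 3586 to 2262 (adjusted p = 3.24e-08) and Dlat of pyruvate dehydrogenase from 1209 to 664 (adjusted p = 0.000181) in the authors' deposited table. The term for sphingolipid synthesis was lower too (camera adjusted p = 0.000613, and 0.0579 at a correlation of 0.05), though its genes with the smallest p were the fatty acid elongases Elovl5, Elovl6 and Elovl3. Cers2, a ceramide synthase in that term, had a deposited log2 fold change of -0.31 (adjusted p = 0.0301). On the higher side stood regulators of alternative splicing, with 7 of 33 genes higher and 0 lower, among them Dyrk1a (0.42) and Rbfox2 (0.38) as log2 fold changes in the authors' deposited table (camera adjusted p = 0.0213, and 0.516 at a correlation of 0.05).

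Lower expression of fatty acid synthesis genes had the smallest p of the list tests, and a hypothesis is that it follows from the loss of Huwe1. A longer fast of the knockout mice before harvest also lowers these genes, but it raises PPAR-alpha targets, whose list had a median log2 fold change of -0.62 with 11 genes lower and 0 higher. This argues against a longer fast unless the knockout itself lowers PPAR-alpha targets. Removing the trend with gene length and level left the list's median at -1.03 (camera adjusted p = 1.44e-36). Class medians of that trend ran only from -0.08 to 0.17 by level and from -0.05 to 0.09 by length. Subtracting them could not have removed the fall. The small size of the trend, rather than this test, argues against it as the cause. A different hour of harvest may also contribute and cannot be told apart from genotype here, since 6 of 19 clock genes were called, in both directions, and the labels give no harvest time.

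The rise of acute phase genes may come from some livers of a group far above the others, since the median implied standard error of the list was above that of 100% of matched random lists. That value does not mark this list, as 31 of 41 lists lay above 95% of theirs, among them lists with few or no called genes, such as the interferon-stimulated genes at 100%. Reads of infiltrating neutrophils are argued against as the source for Hpx, Itih4 and Orm2, which rose by 74340.3, 18489 and 10279.8 normalized reads, while the neutrophil markers together rose by 171, at most 1.66% of any of these. For Saa3 and Socs3, which rose by 202 and 152, such reads cannot be told apart from a change in hepatocytes. The same sum reached 113% of the rise of Socs3, the smaller of these. Folds of low genes such as S100a9 and Retnlg are understated, so the sum may be too low. Lcn2 rose by 2507, far above that sum, but its spread is wide, so the source of its rise is left open too. Whether inflammation in a few livers or the genotype in all of them lies behind the rise stays open, as values per liver were not analysed here.

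The mild fall of genes of the mitochondrial inner membrane could be in part a technical trend, since fold changes rose with gene length, from a median of -0.05 in the shortest of 5 classes to 0.09 in the longest, and fell with level, from 0.17 in the lowest of 8 classes to -0.08 in the highest. With that trend removed the term's median moved from -0.18 to -0.12 and its camera adjusted p from 3.67e-07 to 0.00519, so 66% of the median was left, and the term stayed past the threshold at the same preset correlation. At a correlation of 0.05 the term was not called even before that step (adjusted p = 0.196). How much of the fall the trend accounts for therefore cannot be told apart from an effect of genotype. Whether a lower share of hepatocytes contributes is not settled by their markers. Their median log2 fold change of 0.18 lay above the term's by more than their SD of 0.26, so they did not fall with it. Yet medians of some other cell types lay higher still, such as 0.30 for stellate cells and 0.31 for T and NK cells. That of endothelial cells was 0.05. Raw medians of lists at different levels are hard to compare, as low genes tended to rise. Against random lists matched on level, the median of hepatocyte markers lay above 91.5%. Stellate markers lay above 99.4%, T and NK cell markers above 94.2% and endothelial markers above 62.3%. Values scaled between libraries can also hide a modest loss of the most abundant cell type. Camera did not call the hepatocyte list with log2 fold change as the statistic (adjusted p = 0.14).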
